A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

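The series compares 2 Schizosaccharomyces pombe strains, wild-type and subtelomere-deleted SD5, with 1 array each. Which strain each array measured was taken from its title and genotype label. Per the labels' protocols, total RNA was extracted with Trizol and polyadenylated RNA was purified on an oligo dT column. Biotinylated cRNA was made with the GeneChip 3′ IVT Express kit from 5 ng of this RNA with the steps meant for 250 ng of total RNA, and in vitro transcription ran for 4 hours at 40 °C. This amplification starts at the poly(A) tail and favours signals from the 3′ parts of transcripts. Per the submitters' processing notes, GCOS 1.4 was used, with no role given. Each array measured 1 RNA sample, so a strain and its culture cannot be separated.

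The deposited values are linear intensity values, 1 per probe set and array, in a table of 10928 rows. The summary of probes into probe sets, the scaling target and the mask that the authors applied are not given in the sources used here. In both arrays 5748 rows were exactly 0, and no row was 0 in only 1 array. None of the 2914 probes matched to an S. pombe gene was at 0, and 2601 of the 2624 unmatched probes were; these rows were left out as masked. Of the 5180 rows above 0, 181 were control or reporter probe sets and 4999 were taken as S. pombe probe sets. The depth of an array is its signal over background, given with the results, and the number of arrays limits the precision.

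Genes were named through the platform's probe table, whose gene identifiers were matched to the S. pombe reference annotation, assembly ASM294v3. The table held 5538 probes, 5518 with 1 gene symbol and 20 with several, and 5177 further array rows had no symbol. In all, 2914 probes matched 2896 S. pombe genes, of which 2890 were protein-coding, out of 5124 protein-coding genes in the reference. The current symbol differed from the table's for 113 genes, for example nhe1 and say1. Of the S. pombe probe sets above 0, 2062 had no gene name here and entered counts of probe sets only. The array's genome build is not given in the sources used here, so no coordinates were used. A gene's position is its order among the protein-coding genes counted from the nearer end of its chromosome, left being the end where the reference's coordinates start.

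The background of each array was the 95th percentile of 79 probe sets without an S. pombe target, 32 control and 47 reporter probe sets. The design written before the data were examined took probe sets that match no S. pombe gene, with the 10th percentile of probe sets in reserve. Since the masked rows were all 0, the unmasked control and reporter probe sets were used, a choice made after seeing the data, and the 10th percentile of S. pombe probe sets was added as an alternative. Signals below background were set to it before log2, and log2 ratios of SD5 over wild-type were centred on the median of probe sets above background in both arrays. A probe set below background in 1 array gave a bound, written as at least N-fold, and below background in both arrays no ratio. A bound pointing the wrong way counted as no ratio, a rule also set after seeing the data, and keeping such bounds was added as an alternative. A probe set was called lower or higher at 2-fold. A gene's ratio is the mean over the probe sets that the platform's table gives to it alone, which can carry the suffix of probes that match several genes; 7 genes had a pair of probe sets with signals above 256, which differed by a median of 0.02 and at most 0.17 in log2 ratio.

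For position groups and gene lists, the median log2 ratio was set against 10000 random lists of the same size matched on mean log2 signal in 20 classes, fewer where a list filled much of a class. A median below the 2.5th or above the 97.5th percentile was taken to stand apart, as a description of these arrays. Intervals of medians are 95% order-statistic intervals over genes, which are not replicates. The 24 gene lists were fixed before the data were examined. They cover stress response, chaperones, cytosolic ribosomal proteins, histones, nitrogen starvation, iron uptake, phosphate, zinc and copper, hexose uptake and glucose repression, galactose, thiamine, glycolysis, meiosis, mating, heterochromatin, telomeres, retrotransposons, sterol synthesis, flocculation, G1/S transcription, DNA repair, selection markers, subtelomeric helicases and the mitochondrial genome. Named genes were chosen by a rule fixed at the same time. It took the 12 lowest and 12 highest ratios among genes measured in both arrays, and the 6 brightest genes lost or gained. It added the 3 outermost genes in each array at each end of chromosomes I and II, up to 2 lowest and 2 highest members of each list and position group, and members of the marker, helicase, heterochromatin and telomere lists. The genes str1, ade5, tea2, mug62, pol4 and mug93 lie outside that rule and were named after their values were seen.

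Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (loess with a span of 0.3) and matplotlib 3.10.9. The calls were tested on simulated data for the comparison of SD5 with wild-type, with 4999 probe sets of which 50 each were raised 3-fold and 8-fold and 50 each lowered 3-fold and 8-fold. In each of these 4 sets, 100% of the probe sets were recovered, none of the unchanged was called lower and 14 were called higher. The changed probe sets were all well above background, so recovery at dim signals was not tested. A simulated list of 22 genes shifted by -0.15 lay at the 0th percentile of random lists, and the same list unshifted at the 58.9th. Its genes were drawn at random with independent noise, and the shift was applied to their ratios directly. It therefore checks the calculation only, and not a list of neighbouring genes. The alternatives were no centring, centring on hybridisation controls, quantile and loess normalization, other backgrounds, the background added as a pseudocount, no background filter, other fold thresholds, leaving out probe sets that can match several genes, and other summaries of a gene.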

Results

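Messenger RNA was measured in 2 strains of the fission yeast Schizosaccharomyces pombe, both of mating type h-. The labels name them JP1225, the wild-type, and ST3479, called SD5, a strain whose subtelomeres had been deleted. Subtelomeres are the chromosome regions next to the telomere repeats. Cells of both strains were collected in exponential growth in YES, a rich yeast extract medium, at 32 °C. Each strain was measured on 1 array, so there were no replicates, no test was made, and every ratio below describes these 2 arrays. The comparison addresses which transcripts had a different level in the strain labelled as subtelomere-deleted. Which subtelomeres it lacks is not given in the sources used here.

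The 4999 S. pombe probe sets had a median signal of 1168 in the wild-type array and 998 in the SD5 array. Probe sets without an S. pombe target put the background at 17.7 in the wild-type and 26.6 in SD5. In the wild-type, 4934 probe sets (98.7%) lay above it, and in SD5 4848 (97.0%). Ratios were centred on their median, which was -0.20 on the log2 scale before centring (0.869-fold). The probe sets of the bacterial and phage RNAs added as hybridisation controls were shifted by a similar -0.15, as the median of 27 probe sets. The control probe sets at the 3′ and 5′ parts of the actin mRNA, which show how complete the labelled RNA was, had a 3′ to 5′ ratio of 2.18 in the wild-type and 2.33 in SD5. After centring, 99.1% of the probe sets measured in both arrays lay within 1.5-fold of each other. All folds and log2 ratios below are after centring, with SD5 over wild-type as the direction of the log2 ratio.

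The signals of 7 named genes next to ends of chromosomes I and II were below background and at least 2-fold lower in SD5, while most other transcripts had close levels in both arrays. Of the 4999 probe sets, 40 (0.80%) had a signal at least 2-fold lower in SD5 and 3 had a signal at least 2-fold higher. Of the 40, 34 were below background in SD5 and 26 were at least 4-fold lower. The 7 named genes, with 8 of the probe sets, lay within 24 protein-coding genes of an end of chromosome I or II. None of the 2624 named genes more than 100 genes from an end was 2-fold lower or higher. The other 32 lower probe sets had no gene name here, so their place in the genome is not known from these data.

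**Figure D1:**
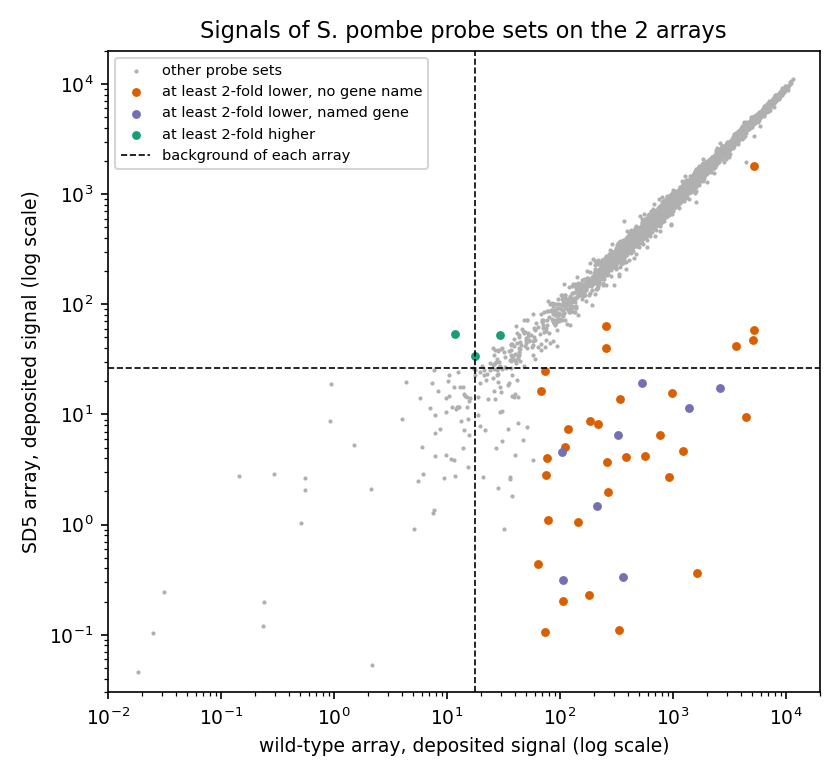
Signal of each S. pombe probe set in the wild-type array (x axis) and the SD5 array (y axis), both on log scales in the deposited intensity units, with dashed lines at the background of each array. The 40 probe sets at least 2-fold lower in SD5 form the cloud below the diagonal, with 8 probe sets of named genes in purple and 32 without a gene name in orange, and the 3 at least 2-fold higher have dim signals.

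The galactose genes at the right end of chromosome II were the most prominent named group. The gene of galactokinase, gal1 (SPOM_SPBPB2B2.13), had a signal of 1404 in the wild-type and 11.5 in SD5, at least 45.8-fold lower. Its neighbour gal10 (SPOM_SPBPB2B2.12C), which encodes UDP-glucose 4-epimerase, had 212 and 1.49, at least 6.94-fold lower. The uridylyltransferase gene gal7 (SPOM_SPBPB2B2.10C) had 536 and 19.3, at least 17.5-fold lower. These genes are the 12th, 13th and 15th protein-coding genes from that end in the reference assembly ASM294v3. The galactose list held 4 genes, of which 3 were lower and 1 was not. The exception was mel1 (SPOM_SPAC869.07C), the alpha-galactosidase gene, which lies on chromosome I and had 82.1 and 44.6 (log2 ratio -0.68). The list's median log2 ratio was -3.46 with genes below background at their bound, lower than in any of 10000 random lists matched on signal.

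At the left end of chromosome I, the signal of nhe1 (SPOM_SPAC977.10), the gene of the plasma membrane sodium/proton antiporter, was 2611 in the wild-type and 17.3 in SD5. That is at least 85.2-fold lower, the largest bound among named genes. The dihydroxyacetone kinase gene dak2 (SPOM_SPAC977.16C), 24th from the same end, had 330 and 6.46, at least 10.8-fold lower. On the right arm of chromosome II, say1 (SPOM_SPBPB2B2.02), 21st from the end, had 362 and 0.335, at least 11.8-fold lower. The outermost gene there, tlh2 (SPOM_SPBCPT2R1.08C), encodes a RecQ-type DNA helicase and belongs to a family with near-identical copies at several ends. It had 4 probe sets, of which 1 was below background in both arrays and gave no ratio. The others had wild-type signals of 104, 108 and 40.3 and SD5 signals of 4.61, 0.316 and 4.32, and their mean log2 bound was -1.32. Of these, the probe sets at 104 and 40.3 carry the suffix of probes that can match several genes, so their signal can come from any copy. A fold against a signal below background is a lower bound. With the background raised to the 10th percentile of S. pombe probe sets, dak2 (log2 bound -0.68) and say1 (-0.81) no longer reached 2-fold, and gal10 and tlh2 gave no ratio.

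The outermost named gene still measured in SD5 differed between the ends. At the left end of chromosome I it was ght3, a member of the hexose uptake list, 28th from the end (58.0 in the wild-type and 46.7 in SD5). At the right end of chromosome II it was cao2, 30th from the end (461 and 397, log2 ratio -0.01). The right end of chromosome I had no named gene with a ratio outside mel1, 24th from the end. At the left end of chromosome II the hexose transporter gene ght7, 13th from the end, had 31.1 and 10.9, and grt1, 15th from the end, had 42.7 and 8.30. Both were below background in SD5, but their wild-type signals were too dim for a 2-fold bound (log2 bounds of -0.02 and -0.48). With the background at the 75th percentile both passed it, with bounds of -1.17 for ght7 and -1.63 for grt1. The enolase gene eno102, 19th from that end, was measured in both arrays at 974 and 538 (log2 ratio -0.65). On chromosome III no named gene was 2-fold lower, and nic1, 5th from the left end, and ade5, 9th from the right end, were measured in both arrays.

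**Figure D2:**
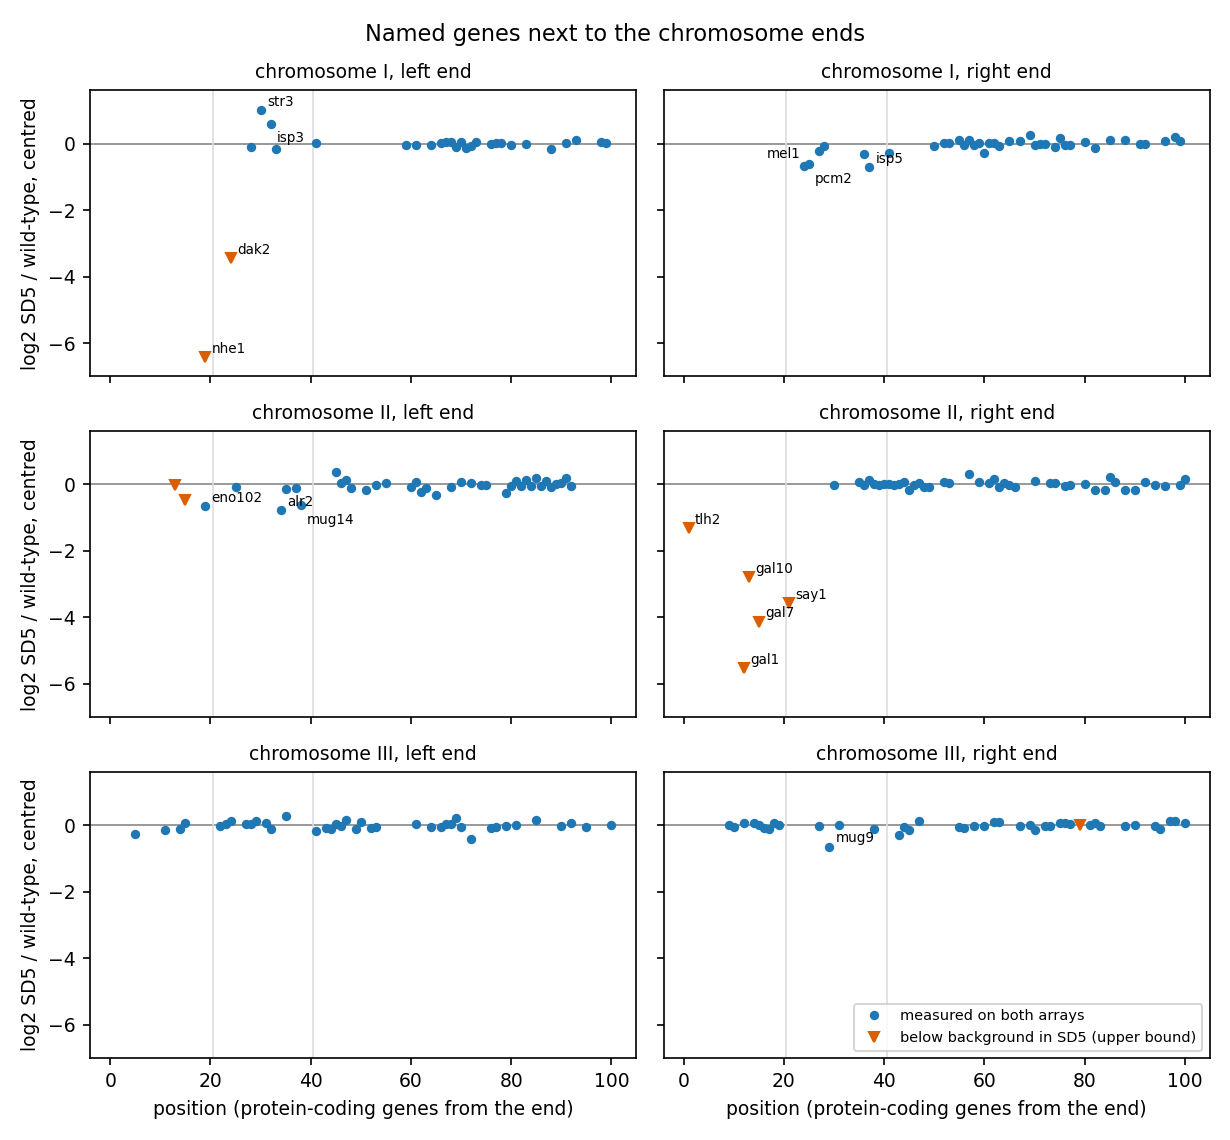
Centred log2 ratio of SD5 over wild-type signal (y axis) against the position of each named gene, counted in protein-coding genes from the chromosome end in ASM294v3 (x axis), 1 panel per end, 1 array per strain. Circles are genes measured in both arrays and triangles genes below background in SD5, drawn at their upper bound; the 7 genes at least 2-fold lower lie at the left end of I and the right end of II, at positions up to 24.

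Pooled over the ends of chromosomes I and II, the median ratio was lowest at positions 1 to 20 and lower than in matched genes at 21 to 40. Of the 80 protein-coding genes at positions 1 to 20, 8 had a named ratio, of which 5 were at least 2-fold lower. The median log2 ratio was -2.06 with genes below background at their bound. Only 1 of the 8, eno102, was measured in both arrays (-0.65). At positions 21 to 40, 24 of 80 genes had a ratio, of which 2 were 2-fold lower and 1 higher, with a median of -0.12, at percentile 0.01 of matched random lists. The 22 of these measured in both arrays had a median of -0.10 (95% order-statistic interval -0.32 to 0.01; percentile 0.09), and 16 of them were below 0. The random lists drew genes singly from the whole genome, so these percentiles take no account of neighbouring genes that vary together. At positions 41 to 60 the median was 0.01 over 33 genes, at 61 to 80 -0.01 over 51 genes and at 81 to 100 0.01 over 37 genes, all inside the range of random lists. The 2227 genes beyond had a median of 0.00.

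Among genes measured in both arrays, which leaves out dak2 and say1, the low median at positions 21 to 40 came from the right end of chromosome I and the left end of chromosome II. At the right end of I all 6 measured genes were below 0 (median -0.47). They included the amino acid permease gene isp5 (124 in the wild-type and 65.4 in SD5, log2 ratio -0.71), mel1 (-0.68), the protein-isoaspartate methyltransferase gene pcm2 (-0.62) and the proline permease gene put4 (-0.24). At the left end of II all 5 were below 0 (median -0.15), with the alanine racemase gene alr2 at 193 and 98.2 (-0.77) and mug14 at 336 and 189 (-0.63). At the left end of I the median of 4 genes was 0.25 and at the right end of II that of 7 genes was 0.01. Without the right end of I the median of the other 16 genes was -0.03 (percentile 17.9), and without the left end of II that of the other 17 genes was -0.03 (percentile 18.2). The split by end was made after the values were seen, and with the background at the 10th percentile of S. pombe probe sets the median of genes measured in both arrays lay at percentile 4.94.

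More than 100 genes from the ends, no named gene reached 2-fold, and the lowest ratios belonged to genes of varied functions. This depended on the processing: 5 such genes (tea2, mpf1, atf31, spo6 and mug27) were 2-fold higher after quantile normalization. With the background at the 75th percentile mug62 and pol4 were higher and mug93 lower, and mug93 was also lower with genes below background kept in. The lowest were ssp1, a calmodulin-dependent kinase kinase gene on chromosome III (594 in the wild-type and 331 in SD5, log2 ratio -0.64), and clr4, the gene of the histone H3 lysine 9 methyltransferase (254 and 150, -0.56). The proteasome ATPase gene rpt5 (696 and 413, -0.55), the bouquet gene bqt2 (57.9 and 34.7, -0.54) and ste7 (244 and 150, -0.50) followed. On chromosome III, 29th from the right end, the meiotic gene mug9 had 144 and 80.2 (-0.64). For scale, probe sets as bright as that of ssp1 had a robust SD of 0.12 around their median ratio, and the dimmest class one of 0.33. That is a spread between probe sets within this pair of arrays, which is not a replicate error.

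The highest ratios included several genes of iron uptake. The siderophore and heme transporter gene str3, 30th from the left end of chromosome I, had 29.7 in the wild-type and 52.1 in SD5 (log2 ratio 1.02), the only named gene at least 2-fold higher. On simulated arrays 14 unchanged probe sets were called higher at 2-fold. The simulated noise at dim signals also came from control probe sets and from signals below background. The 14 therefore cannot decide whether the 3 here are changes. With 1 array per strain, none of the 3 can be taken as a change. The ratio of str3 fell short of 2-fold without centring (0.81), after loess normalization (0.94), with the background as a pseudocount (0.92) and with centring on hybridisation controls (0.96). Next came fio1, the gene of the iron-uptake ferroxidase, with 372 and 575 (0.83), and its adjacent partner fip1, the iron permease gene, with 108 and 152 (0.69). The siderophore transporter gene str1 had a ratio of 0.45. Dim genes made up most of the other high ratios, such as spo6 (41.1 and 63.4, 0.83), mpf1 (48.5 and 71.9, 0.77) and mug27 (20.6 and 27.6, 0.62). Brighter ones were nsk1 (195 and 260, 0.62) and trm13 (186 and 237, 0.55). The other 2 probe sets at least 2-fold higher had no gene name and dim signals, 17.7 and 33.7 in one and 11.9 and 53.3 in the other. The split of 40 lower and 3 higher probe sets depended on scaling: it was 33 and 17 after quantile normalization and 44 and 1 without centring.

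Of 24 gene lists, 21 had members with a ratio, and the medians of 6 lay outside the central 95% of random lists matched on signal. By the definition of that range, some of 21 lists can lie outside it by chance alone. The random lists again drew genes singly, so these percentiles take no account of members that vary together, such as the adjacent genes fip1 and fio1. Iron uptake genes had a median log2 ratio of 0.15 (11 genes, 7 above 0, 95% order-statistic interval -0.056 to 0.83, percentile 99.8), relative to the shift of all probe sets that centring removed; without centring it was -0.055, still at percentile 99.8. Of these 11 genes, 1 was at least 2-fold higher and none 2-fold lower. The 8 iron uptake genes over 100 genes from an end had a median of 0.18. With the background at the 10th percentile of S. pombe probe sets, which leaves out the dimmest members, the list lay at percentile 96.0. Cytosolic ribosomal protein genes had a median of 0.07 over 119 genes, of which 111 were above 0. Random lists matched on signal lay above 0 as well, with their central 95% from 0.032 to 0.047. After loess normalization, which removes a trend with signal, the median of the ribosomal protein genes was 0.0061. It was -0.13 without centring and 0.0040 after quantile normalization, and it stayed at percentile 99.4 or above under the 12 alternatives. These genes are among the brightest, and a list that fills much of a signal class was matched in wider classes. The percentile therefore cannot show that ribosomal protein genes stand apart from genes of equal signal.

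**Figure D3:**
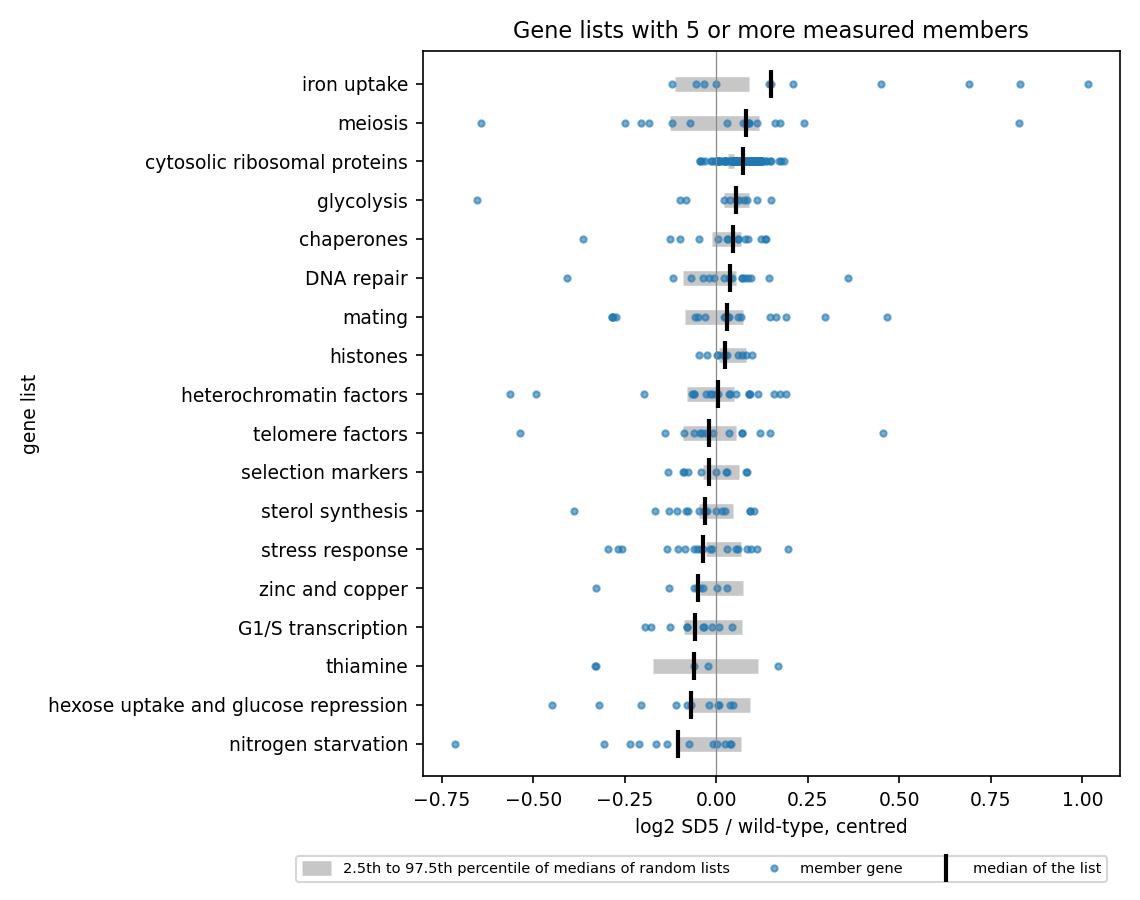
Centred log2 ratio of SD5 over wild-type signal (x axis) for the members (dots) of the 18 gene lists with 5 or more measured members (y axis), with the list's median (black bar) and the central 95% of the medians of random lists matched on signal (grey). Iron uptake (median 0.15) and ribosomal protein genes (0.07) lie above the grey range, and nitrogen starvation (-0.10), stress response (-0.04) and zinc and copper genes (-0.05) below it.

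Besides galactose genes, the lists on the low side had small medians. Stress response genes had a median of -0.04 (19 genes, 12 below 0, percentile 0.87), with tms1 at -0.30 and gst1 at -0.27. The 15 members over 100 genes from an end had a median of -0.02 (percentile 9.88), and after loess normalization the list lay at percentile 5.73. Zinc and copper genes had a median of -0.05 (8 genes, 6 below 0, percentile 1.82), with the copper transporter gene ctr4 at 5941 in the wild-type and 4112 in SD5 (-0.33). Its 7 members over 100 genes from an end had a median of -0.04 (percentile 2.69). This list lay at percentile 7.53 after loess and 7.94 after quantile normalization. Nitrogen starvation genes had a median of -0.10 (12 genes, 8 below 0, percentile 2.24). Their lowest members included isp5 and put4 next to the right end of chromosome I, and the 10 members far from the ends had a median of -0.04 (percentile 29.6). This list lay at percentile 8.70 with the background at the 10th percentile of S. pombe probe sets and 2.52 with the brightest probe set of each gene. No member of the stress, zinc and copper or nitrogen lists was 2-fold lower or higher.

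Genes of heterochromatin and of telomeres, whose products act at chromosome ends, stayed below 2-fold in both directions. The 21 heterochromatin factors had a median of 0.00 (percentile 73.8). Besides clr4, the demethylase-like gene epe1 was low (136 in the wild-type and 84.3 in SD5, -0.49), while swi6 (0.09), chp1 (0.19), chp2 (0.17) and clr3 (-0.06) were closer to 0. The 14 telomere factors had a median of -0.02 (percentile 50.8), between bqt2 at -0.54 and the shelterin gene ccq1 at 0.46 (689 and 821). Among the others were taz1 (-0.06), rap1 (-0.14), rif1 (0.12), pot1 (0.04) and the telomerase catalytic subunit gene trt1 (0.15). The genes usually used as selection markers had a median of -0.02 over 10 genes. The 4 probe sets of ura4 were below background in both arrays, at up to 12.5 in the wild-type and 24.2 in SD5.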

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

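Reporter probe sets have no S. pombe target and entered no comparison, and 2 of them had a signal above the SD5 background and at least 2-fold above the wild-type. The first had 2.47 in the wild-type and 33.6 in SD5, at least 2.18-fold higher. The second had 5.26 in the wild-type and 38.7 in SD5, at least 2.52-fold higher. Both belong to the 79 probe sets that set the background, and 4 of these lay above it in each array by the definition of a 95th percentile.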

How the results depend on the processing

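The settings of centring on hybridisation controls, of the background at the 10th percentile of S. pombe probe sets and of keeping bounds that point the wrong way were chosen after seeing the data. Medians at positions 1 to 20 of chromosomes I and II stayed between -4.49 and -2.06 and those at 21 to 40 between -0.32 and -0.065 under 12 alternatives, below the 2.5th percentile in each. For genes 21 to 40 measured in both arrays the range was -0.30 to -0.051, with percentiles from 0.02 to 4.94. Galactose genes stayed between -5.66 and -2.90 under 11 alternatives. The former came from keeping genes below background in at their own signals, so it rests on SD5 signals below background. With the background at the 10th percentile of S. pombe probe sets, galactose and flocculation had under 3 members and gave no value.

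Without centring every ratio shifts by the -0.20 that centring removes, so values moved by construction. Ribosomal protein genes then had -0.13 and iron uptake genes -0.055, opposite in sign to the centred values. Under this setting the medians were -0.19 for genes 41 to 60, -0.21 for 61 to 80, -0.19 for 81 to 100 and -0.20 beyond. Those of lists were -0.24 for stress response, -0.16 for chaperones, -0.18 for histones, -0.31 for nitrogen starvation, -0.15 for glycolysis, -0.12 for meiosis, -0.17 for mating, -0.20 for heterochromatin, -0.22 for telomeres, -0.24 for sterol synthesis, -0.26 for flocculation, -0.26 for G1/S transcription, -0.16 for DNA repair and -0.22 for selection markers, and 1 probe set was 2-fold higher. Centring on hybridisation controls gave -0.063 for genes 61 to 80, -0.038 for 81 to 100, -0.051 beyond, 0.020 for ribosomal proteins and -0.029 for histones. Quantile normalization gave 17 probe sets 2-fold higher, 0.0097 for genes beyond 100, 0.0040 for ribosomal proteins, 0.19 for meiosis and 0.089 for flocculation. Loess gave 0.0061 for ribosomal proteins. With the background as a pseudocount, 1 probe set was 2-fold higher, ribosomal proteins had 0.054 and meiosis genes 0.15. The cause was not tested for the last 3 settings.

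Counts followed the background and the threshold. The 40 lower probe sets became 63 at 1.5-fold, 73 with no background filter and 14 with the background at the 10th percentile of S. pombe probe sets; all 14 were among the 40, and the higher background leaves fewer to call. The 3 higher became 19 at 1.5-fold, 1 at 3-fold, 23 with no filter, 12 with the background at the 75th percentile and 0 at the 10th percentile of S. pombe probe sets. Signal over background limits the bounds: dim genes can show no large fold. Among named genes, 202 of 1632 values moved by more than the spread at their signal, 142 of them without centring. The sign changed in 103 values, 56 of them without centring (eno101 from 0.11 to -0.091, for example), and in none of a gene past 2-fold. Position groups by distance in kb were not run, because coordinates were not used. No paired analysis was possible because each strain had 1 array.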

Other observations

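The test of the position of iron uptake genes and the split of genes 21 to 40 by end were chosen only after the values were seen. Genes of mating and meiosis, which are usually low in growing h- cells, had no common direction. The 18 mating genes had a median log2 ratio of 0.03 (percentile 83.5), from -0.29 in the G protein gene gpa1 (717 in the wild-type and 511 in SD5) to 0.47 in the pheromone precursor gene mfm1 (60.8 and 72.0). The 17 meiosis genes had a median of 0.08 (percentile 93.3), with spo6 and mug9 at the extremes. Genes of hexose uptake and glucose repression had a median of -0.07 (11 genes, percentile 3.10), with percentiles from 1.57 to 44.7 under 12 alternatives, so on which side of the 2.5th it lay depended on the processing. The percentile also rested on counting bounds that point the wrong way as no ratio, a rule set after the values were seen, and with such bounds kept it was 18.7. The list held the invertase gene inv1 at 68.2 and 43.4 (-0.45) and the fructose bisphosphatase gene fbp1 at 193 and 134 (-0.32). The 5 thiamine genes had a median of -0.06 (percentile 29.5), with nmt1 and thi9 both at -0.33.

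Other lists stayed inside the range of random lists. Their medians were 0.04 for chaperones (14 genes), 0.02 for histones (11), 0.05 for glycolysis (11), -0.03 for sterol synthesis (16), -0.05 for flocculation (4), -0.06 for G1/S transcription (10) and 0.04 for DNA repair (16). The helicase list had 1 measured gene, tlh2. Phosphate, retrotransposon and mitochondrial genes had no named ratio and were not analysed here. In the glycolysis list, eno102 next to the left end of chromosome II had -0.65 while its paralog eno101, far from the ends, had 0.11. On chromosome III the only position group outside the range of random lists was that of genes 41 to 60, with a median of -0.05 over 18 genes, 14 of them below 0 (percentile 1.43), and ubp12 lowest at -0.29. This group lay inside that range after loess (percentile 2.70) and quantile normalization (3.35).

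Of the 9 lower probe sets with a wild-type signal over 1000, 7 had no gene name here, and 4 of these 7 stayed above background in SD5. The SD5 signals of these 4 were 1816, 58.6, 47.4 and 42.2. All but the first were close to 41.5, the highest SD5 signal of a probe set without an S. pombe target. The largest bound among the 7 was that of a probe set with 4411 in the wild-type and 9.58 in SD5, at least 144-fold lower, and another had 5236 and 58.6, 77.7-fold lower. Of the 40 lower probe sets, 13 carry the suffix of probes that can match several genes, and without all such probe sets 27 were lower.

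Named genes 21 to 40 from the ends of chromosomes I and II that were measured in both arrays had a lower median than matched random lists (-0.10, interval -0.32 to 0.01). A trend with signal is argued against as the whole cause, since after loess normalization the median was -0.088. Its percentile (0.21) does not bear on this, because the random lists were already matched on signal. As a set, 41 nitrogen, stress and meiosis genes far from the ends were not lower. Their median was 0.0017 (interval -0.071 to 0.058; percentile 48.9), with 20 of them below 0. By list, the far members had medians of -0.04 for nitrogen starvation, -0.02 for stress response and 0.08 for meiosis. The pooled median mixes these directions, and its interval overlaps that of genes 21 to 40, so it cannot decide on a growth difference. Such a difference, also one that lowers only some of these genes, stays open. An effect of the deleted ends that falls off with position stays open as well: the medians were -0.010 for genes 61 to 80 and 0.014 for genes 81 to 100, but without the right end of I or without the left end of II the median lay inside the range of random lists (percentiles 17.9 and 18.2), and which subtelomeres SD5 lacks is not given in the sources used here. Other differences between 2 single cultures and cross-hybridisation with deleted copies stay open too, since each strain had 1 array and the test of shared probe sets was void, with 0 members measured by one.

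Iron uptake genes had a higher median than matched random lists after centring (0.15, interval -0.056 to 0.83), but 4 of 11 were below 0, and with the background at the 10th percentile of S. pombe probe sets the list lay inside their range (percentile 96.0). A trend with signal is argued against as the whole cause, since after loess normalization the median was 0.17. Its percentile (99.96) does not bear on this either, as the random lists were matched on signal. Position next to the deleted ends is argued against as well, since the 8 members over 100 genes from an end had a median of 0.177 (percentile 99.9), although 5 of them were above 0 and str3, the highest, lies 30 genes from an end. A difference in iron between the 2 cultures and an effect of the strain stay open, as 1 array per strain cannot separate them.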
